A study of Homo sapiens with 4 samples.

How the data were processed

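The series covers 4 libraries: chromatin of DU145 cells pulled down with an antibody to CTCF, chromatin of DU145 cells pulled down with an antibody to acetylated lysine 27 of histone H3 (H3K27ac), and input chromatin of DU145 and of LNCaP cells. DU145 and LNCaP are established human prostate cancer cell lines. The labels give 1 library for each, so there are no replicates. The peak lists of the DU145 CTCF and DU145 H3K27ac libraries were analysed. Signal of the input libraries was not analysed here, except as far as the peak values carry it. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication, and sequencing libraries were made from the recovered DNA.

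Per the submitters' processing notes, Bowtie and MACS2 were used and the genome build was hg19; versions and settings are not given in the sources used here. Each list was called on 1 library, as each belongs to 1 sample in the labels. Both lists have the columns of a MACS2 narrow peak list. For each peak the authors deposited a start, an end and a summit offset, a whole-number score, a fold enrichment (a linear ratio of fragments at the summit to local background), and the −log10 of a p-value and of a q-value. The smallest −log10 q was 1.31 in both lists, so neither held a peak with a q-value above 0.05. Fold enrichment is the authors' own value for each peak. It was used only within 1 list: to describe, rank, filter or test peaks, to score domains and to solve for fragment numbers. It was not compared between the lists. Positions are given in hg19 and count from 1.

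The deposited fold and −log10 p of a peak both depend on the number of fragments at its summit and on its local background. The values fit a fold with 1 added to both the scaled fragment number and the background, so a fold is smaller than their plain ratio. Solving for both gave a whole number of fragments per peak and its background. For CTCF this required multiplying fragment numbers by 0.911, the scale at which the values came out whole; for H3K27ac the scale was 1. With a tolerance of 0.002 on −log10 p, 99.9972% of CTCF peaks and 100% of H3K27ac peaks were solved. At a scale 3% off, 0.401% and 0.741% were. The lowest background, shared by 30.9% of CTCF and 30.6% of H3K27ac peaks, was taken as the genome-wide background of each list; it was 2.18 and 3.18 fragments. The scales gave 1.10 CTCF reads and 0.778 H3K27ac reads per input read. The labels do not say which of the input libraries served as background for which list, so input here means the background library used by the authors. Both lists gave 0.0142 input fragments per base, on the assumption that the smallest peak width (154 bases for CTCF, 288 bases for H3K27ac) was the fragment length used. With an effective genome of 2.7 Gb, also an assumption, this came to 42.0 M CTCF, 29.8 M H3K27ac and 38.3 M input reads. The 2 estimates of input fragments per base differed by 7.9e-05%, as 1 input library behind both lists would give. Which library that was is not known. The solved fragment numbers set the precision of single peaks: the median was 45 fragments at a CTCF summit and 23 at an H3K27ac summit, and exact Poisson intervals are given for the strongest peaks. All intervals cover counting error only.

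Overlap was counted from 1 shared base. Chance was estimated by moving the peaks of 1 list along their chromosome by a random distance, with wrapping at the end, and counting again (1000 shifts). The two-sided permutation p is the doubled share of shifts at or beyond the observed value, and the smallest p that 1000 shifts can give is 0.002. Circular shifts do not keep peaks in their neighbourhood, so local shifts of 20 to 200 kb in either direction were added as a second chance level. Each share is given with its Wilson interval at a confidence level of 95%. The difference in CTCF fold enrichment between peaks with and without H3K27ac was the difference of medians, against the same shifts. H3K27ac peaks within 12.5 kb of each other were joined into domains, and domains were ranked by the sum of fold enrichment times peak width in kb. Domains past the point where the ranked curve, with both axes scaled to 1, reaches a slope of 1 are called large domains. CTCF peaks were also split into 10 equal groups (deciles) by fold enrichment, with 200 local shifts for each. H3K27ac coverage at a CTCF summit is the percent of summits that lie inside an H3K27ac peak; it was set against the same percent 300 bases to either side, with a standard error from 1000 bootstrap resamples of the CTCF peaks. Peaks are not replicates, so the tests, intervals and standard errors describe these 2 lists and not the variation between cultures.

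The peak numbers, the overlap with circular shifts, the CTCF signal comparison, the domains and their alternatives were chosen before the data were examined. The local shifts, the deciles, the coverage at summits, the gaps between peaks, the edges of domains and the densities by chromosome were chosen after seeing the data. The alternatives were stricter lists, other definitions of overlap, lists of equal length, autosomes only, other placements, another signal column, another stitching distance and another ranking, and, added later, local shifts, assembled chromosomes only, peaks of high background left out, and H3K27ac peaks less than 500 bases apart joined.

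The gene annotation used for this work was of another build (GRCh38.p14), and no genome sequence was used. No gene was therefore named from coordinates, which was the rule set in advance for named genes. Of 29 planned results, 25 were not run: transcription start sites, genes with H3K27ac at the start, motifs in both lists, the orientation of motif pairs, and 19 fixed gene lists. The split of the CTCF signal comparison by distance to a start was not run either. The calculations were tested on simulated data. All 5000 simulated fragment numbers were recovered at either of 2 scales (100%). Of 34750 peaks with CTCF widths placed at random, the overlap was 1.04 times the shifted mean, and 9.31 times with 20% of peaks placed on H3K27ac peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.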

Results

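CTCF and H3K27ac were mapped by chromatin immunoprecipitation and sequencing in DU145, a prostate cancer cell line derived from a brain metastasis. CTCF is a DNA-binding zinc finger protein that acts at insulators and at the anchors of chromatin loops. H3K27ac marks nucleosomes at active promoters and enhancers. The series title places the libraries in a study of chromatin interactions associated with RNA polymerase II in prostate cancer. Each mark was measured in 1 library, so no value has a replicate error. The median number of fragments at a summit was 45 for CTCF (range 10 to 308) and 23 for H3K27ac (range 10 to 568).

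The CTCF list held narrow, widely spaced peaks, and the H3K27ac list broader peaks that lay closer together. The CTCF list had 36152 peaks with a median width of 276 bases (quartiles 221 and 351), which covered 11.1 Mb. The H3K27ac list had 50364 peaks with a median width of 566 bases (quartiles 378 and 1017), which covered 43.3 Mb. Of the H3K27ac peaks 25.5% were wider than 1 kb, against 0.221% of the CTCF peaks. The smallest width was 154 bases for CTCF and 288 bases for H3K27ac, so every H3K27ac peak exceeded the median CTCF width. Part of the width difference may thus come from peak calling. The median gap between neighbouring peaks was 34.9 kb for CTCF and 4.08 kb for H3K27ac, and 34.6% of H3K27ac gaps but 3.65% of CTCF gaps were under 1 kb. Short H3K27ac gaps may include breaks inside a region that the caller split. Within each list, the median fold enrichment was 9.52 for CTCF (maximum 57.0) and 4.55 for H3K27ac (maximum 73.3). A −log10 q of 10 or more was reached by 79.8% of CTCF and 43.4% of H3K27ac peaks. At that threshold the order of the peak numbers turned, with 28832 CTCF and 21881 H3K27ac peaks. Depth differed between the libraries, at 1.10 CTCF and 0.778 H3K27ac reads per input read, and q-values depend on depth. How far depth accounts for these shares and numbers was not tested. No test between marks was made. Of the peaks, 462 for CTCF and 582 for H3K27ac lay on contigs outside the 24 assembled chromosomes, mostly on alternative haplotypes of chromosome 6 for H3K27ac (448) and in part for CTCF (214).

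Both marks were densest on chromosomes 19, 17 and 22. Chromosome 19 had 26.5 CTCF and 54.7 H3K27ac peaks per Mb, chromosome 17 had 22.3 and 45.5, and chromosome 22 had 21.6 and 44.3. The autosomes together had 12.4 CTCF and 17.5 H3K27ac peaks per Mb. Among autosomes, chromosome 13 had the lowest densities, with 6.98 CTCF and 6.25 H3K27ac peaks per Mb. H3K27ac peak density varied more between chromosomes than CTCF peak density: there were 2.07 H3K27ac peaks per CTCF peak on chromosome 19 and 0.895 on chromosome 13. Chromosome X had 5.22 CTCF and 4.59 H3K27ac peaks per Mb, 0.420 and 0.262 times the autosomal densities. Among the stronger peaks of each list these ratios were 0.180 and 0.369. The local background was at the genome-wide level for 88.0% of CTCF and 93.5% of H3K27ac peaks on chromosome X, against 29.1% and 28.9% on the autosomes. That level is the lowest background in each list, so input below it would not show. Whether lower input on chromosome X accounts for its densities and ratios was not tested.

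**Figure D1:**
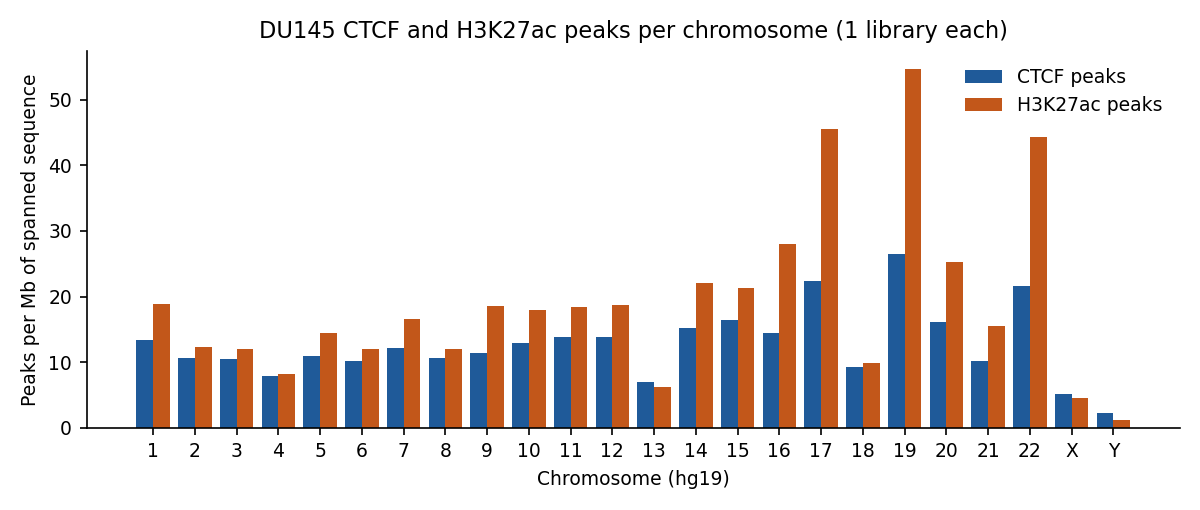
Peaks per Mb of spanned sequence on each hg19 chromosome, with blue bars for CTCF and orange bars for H3K27ac (DU145, 1 library each). Chromosome 19 reaches 54.7 H3K27ac and 26.5 CTCF peaks per Mb, and H3K27ac bars exceed CTCF bars on the autosomes other than chromosome 13.

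The strongest CTCF peak lay at chromosome 16, 60792 to 61243, with a fold enrichment of 57.0 from 198 fragments at the summit (exact Poisson 95% interval 171 to 228). The next were at chromosome 9, 134615310 to 134615911 (fold 49.6, 179 fragments), and chromosome 9, 11107 to 11629 (fold 49.0, 214 fragments). The strongest H3K27ac peak spanned 9460 bases at chromosome 12, 52537750 to 52547209, with a fold enrichment of 73.3 from 305 fragments (interval 272 to 341). It was followed by chromosome 19, 797279 to 802729 (fold 71.6, 298 fragments), and chromosome 12, 122235289 to 122243609 (fold 69.8, 311 fragments). These 3 H3K27ac peaks each overlapped a CTCF peak. Of the 100 strongest peaks of each list, 42 CTCF peaks overlapped H3K27ac and 36 H3K27ac peaks overlapped CTCF.

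The first comparison between the lists asked whether CTCF sites and acetylated regions coincide. A minority of CTCF peaks overlapped an acetylated region, but far more than placement along the chromosome gave. Of 36152 CTCF peaks, 5121 overlapped an H3K27ac peak, 14.2% (Wilson 95% interval 13.8 to 14.5). Circular shifts gave a mean of 2.23% (range 1.83 to 2.79), so the observed share was 6.35 times higher. In the other direction, 5080 of 50364 H3K27ac peaks overlapped a CTCF peak, 10.1% (interval 9.83 to 10.4) against a shifted mean of 1.60%. Both differences had a two-sided permutation p of 0.002, the smallest that the shifts can give. Local shifts of 20 to 200 kb, which keep peaks in the same neighbourhood, gave a higher chance level of 3.92% (range 3.56 to 4.23), and the observed share was 3.61 times that level (permutation p = 0.002).

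Acetylated regions that overlapped CTCF had higher fold enrichments and were wider than the others. Their median fold enrichment was 8.77 (n = 5080) against 4.36 for those without CTCF (n = 45284), and their median width was 917 against 542 bases. These medians were not set against shifts. The share with CTCF was 3.04% in the weakest decile of H3K27ac peaks by fold enrichment, 2.62% in the second, and higher in each decile from there to 24.6% in the strongest (intervals for the weakest and the strongest 2.60 to 3.55 and 23.5 to 25.9). Local shifts gave 1.85% in the weakest and 5.82% in the strongest. Over the shifted level, the share was 1.64 times in the weakest decile and 1.38 times in the second. It was 4.81 times in the ninth decile and 4.23 times in the strongest, so this ratio did not rise throughout. Wider peaks have more room for a CTCF peak, but CTCF summits per Mb of H3K27ac peak differed too. They lay between 17.5 and 31.5 in the 5 weakest deciles, without a steady rise, and went from 47.8 in the sixth to 104.6 in the strongest. The densities per decile were not set against shifts.

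CTCF peaks with H3K27ac had a higher median fold enrichment than the others, but the difference depended on how the comparison was drawn. The median was 11.2 in the 5121 CTCF peaks that overlapped H3K27ac and 9.39 in the 31031 that did not, a difference of 1.81. Circular shifts gave differences from −0.646 to 1.89 (two-sided permutation p = 0.004). Local shifts gave differences from 1.01 to 2.46 with a mean of 1.72 (permutation p = 0.697), so the observed difference lay inside the range for positions in the same neighbourhoods. In another definition, a CTCF peak counted as acetylated only if its summit lay inside an H3K27ac peak. The difference then reversed to −0.874 (permutation p = 0.006 against circular shifts). This reversed difference was not set against local shifts.

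Overlap did not rise steadily with CTCF strength. It was 28.0% in the strongest decile of CTCF peaks (interval 26.6 to 29.5), fell to 10.1% in the fourth decile, and was 16.5% in the weakest (interval 15.4 to 17.8). The chance level differed as well: local shifts gave a mean of 6.40% in the strongest decile, whose peaks had a median width of 418 bases, and 3.36% in the weakest, with 185 bases. Over that level, overlap was 4.38 times in the strongest, 4.92 times in the weakest and 2.89 times in the sixth decile, the lowest ratio of the 10; these ratios were not tested against each other. The weakest decile had fold enrichments between 1.38 and 4.81 and a median of 20 fragments at the summit.

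**Figure D2:**
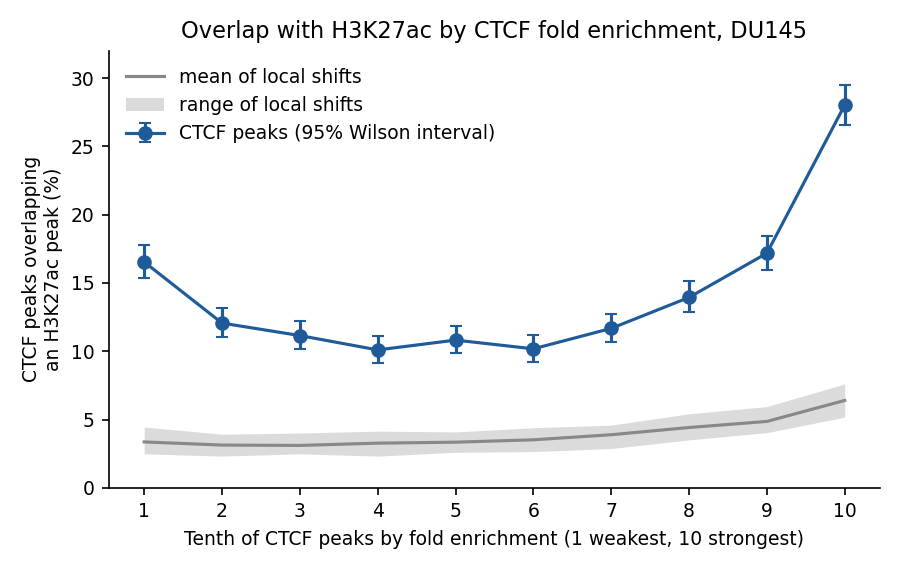
Percent of CTCF peaks that overlap an H3K27ac peak (y axis) in each decile of CTCF peaks by fold enrichment (x axis), with 95% Wilson intervals; the grey line and band are the mean and range of 200 local shifts. Overlap is highest in the strongest decile at 28.0%, where the shifted mean is also highest at 6.40%, and is higher in the weakest decile (16.5%) than in the middle deciles.

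H3K27ac peaks flanked CTCF summits more often than they covered them. Of all CTCF summits 8.40% lay inside an H3K27ac peak, against 11.6% of positions 300 bases to either side, a ratio of 0.724 (bootstrap SE 0.0085). Ratios were computed for the strongest, the middle and the weakest deciles. In the strongest decile 11.6% of summits and 20.8% of flanking positions were covered (ratio 0.560, SE 0.020). In the fifth and sixth deciles the ratio was 0.700 (SE 0.021). In the weakest decile coverage was 14.0% at the summit and 14.0% beside it, a ratio of 1.00 (SE 0.021).

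**Figure D3:**
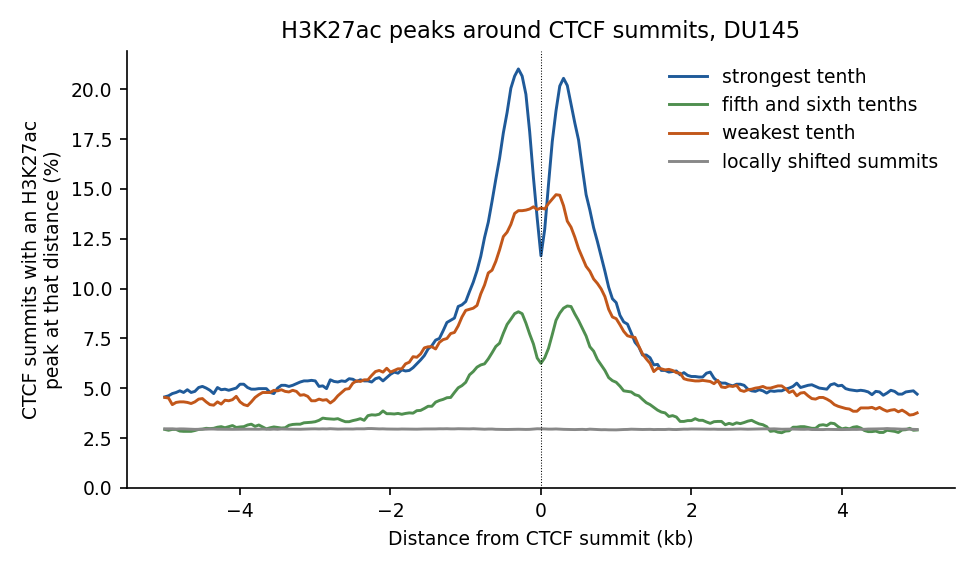
Percent of CTCF summits with an H3K27ac peak at each distance (x axis, kb) for the strongest, middle and weakest deciles of CTCF peaks by fold enrichment and for locally shifted summits. Coverage at the summit is 11.6% in the strongest decile against 20.8% at 300 bases, and 14.0% at both places in the weakest decile.

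CTCF summits were concentrated in short breaks between acetylated regions. Gaps of up to 500 bases between neighbouring H3K27ac peaks held 609 CTCF summits in 3.14 Mb, 194 per Mb, against 25.3 per Mb after local shifts, a ratio of 7.65 (permutation p = 0.002). The excess shrank with gap size. It was 1.95 times for gaps of 500 to 1000 bases and 1.24 times for gaps of 1 to 5 kb (permutation p = 0.002 for each). These longer gaps held 53.3 and 34.3 summits per Mb, fewer than the 70.2 per Mb inside H3K27ac peaks. Local shifts of 20 to 200 kb do not keep summits beside H3K27ac peaks. The fall of the ratio with gap size thus cannot tell breaks from mere nearness to H3K27ac. Gaps of 5 to 20 kb held 24.8 summits per Mb, 0.985 times the shifted mean (permutation p = 0.480). Restriction to the stronger peaks of both lists raised the ratio in the shortest gaps to 13.3.

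H3K27ac peaks were joined into domains to describe where they cluster. Joining neighbouring H3K27ac peaks gave 18213 domains, of which 48.4% were single peaks. The ranked scores passed a slope of 1 at 784 large domains, which had a median length of 36.9 kb and a median of 12 peaks. They held 22.6% of H3K27ac peaks and 36.7% of the total score by which they were chosen, and 12.7 Mb of the 43.3 Mb in peaks. The highest score was at chromosome 19, 1063426 to 1277765, a domain of 214 kb with 96 peaks and 16 CTCF summits. The next were at chromosome 11, 65620851 to 65688984 (68.1 kb, 19 peaks), chromosome 22, 46431255 to 46518975 (87.7 kb, 30 peaks), and chromosome 11, 65237303 to 65278336 (41.0 kb, 9 peaks). The sixth, at chromosome 8, 128806050 to 129012252, spanned 206 kb with 82 peaks and had 2 CTCF summits, and the eleventh, at chromosome 15, 67357199 to 67487485, spanned 130 kb with 53 peaks and had 0. Input signal was not subtracted, and ranking by bases in peaks kept 12 of the 20 domains with the highest scores.

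**Figure D4:**
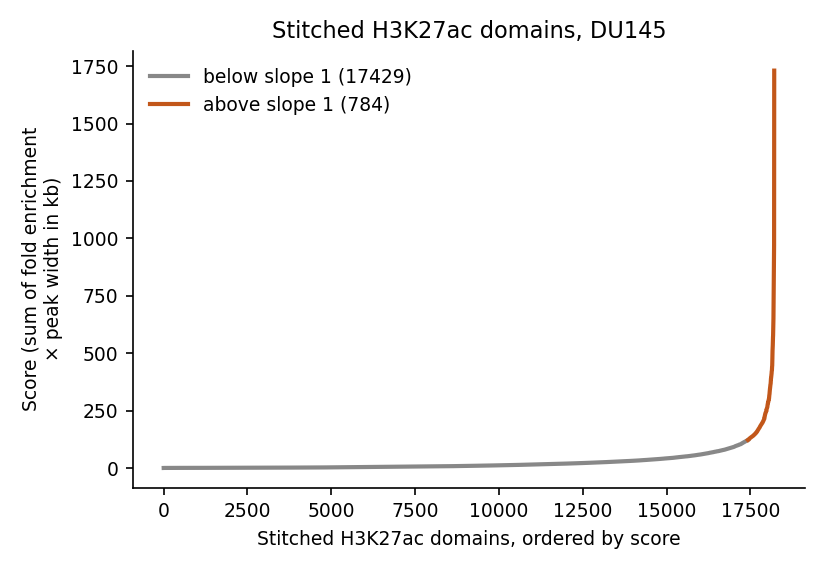
Score of each stitched H3K27ac domain (y axis, sum of fold enrichment times peak width in kb) in increasing order (x axis). The 784 domains past slope 1 are orange and the 17429 others grey.

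Large domains contained more CTCF summits than locally shifted positions gave, but not more per Mb than the other domains. Large domains held 45.5 CTCF summits per Mb and the others 49.3. A CTCF summit lay in 72.4% of the large domains and in 18.5% of the others, which were shorter. The density in large domains was 1.44 times the mean of local shifts (permutation p = 0.002). The H3K27ac peaks in them held 58.1 summits per Mb, 1.86 times their shifted mean (permutation p = 0.002), against 70.2 per Mb in all H3K27ac peaks. Just outside, the first 5 kb from a domain edge held 36.1 per Mb, 1.23 times the shifted mean (permutation p = 0.004). Farther out, from 5 kb up to the distance used for joining, the density was 23.4 per Mb, 0.798 times the shifted mean (permutation p = 0.002). These flanks hold no H3K27ac peak by construction. CTCF summits inside H3K27ac peaks therefore cannot lie in the flanks, but the same summits can after a shift. This lowers both ratios, so 0.798 does not by itself show fewer CTCF sites there.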

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

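Tests with local shifts, assembled chromosomes only or high background left out, and all alternatives for coverage at summits, gaps, domain edges, chromosome X and shared domains, were chosen after seeing the data. Of 68 alternatives, 50 kept their direction and side of the threshold, or their value within its limits. The limits were wide for numbers of peaks and domains and narrow for widths and coverage. With a −log10 q of 10 or more, the 28832 CTCF peaks counted as kept, but their median width of 296 bases as moved. The overlap of CTCF with H3K27ac ranged from 8.40% (summit inside) to 19.9% (within 1 kb), each with permutation p = 0.002. The CTCF fold difference of 1.81 had a permutation p of 0.697 under local shifts, because that chance level itself averaged 1.72. It reversed to −0.874 with the summit inside an H3K27ac peak. The deciles of CTCF peaks show the same turn. Overlap was 28.0% in the strongest and 16.5% in the weakest, but summits inside an H3K27ac peak were 11.6% and 14.0%. What lowers coverage at strong summits was not settled. Stricter lists hold fewer peaks by construction. The stronger 18076 CTCF peaks had a median width of 330 bases and covered 6.73 Mb, and the stronger 25182 H3K27ac peaks 956.5 bases and 31.5 Mb. With a −log10 q of 10 or more, the 28832 CTCF peaks had 296 bases and 9.61 Mb, and the 21881 H3K27ac peaks 1062 bases and 29.5 Mb. The density on chromosome X over that on autosomes went from 0.420 to 0.180 for the stronger CTCF peaks and from 0.262 to 0.369 for the stronger H3K27ac peaks. Coverage at summits over flanks stayed between 0.700 and 0.842, the ratio in short gaps between 7.65 and 13.3, and that beside large domains between 1.21 and 1.23. All domains numbered between 13309 and 27014, and large domains between 691 and 1010. Of the 124 alternatives fixed in advance, 105 were not run: those of start sites, gene lists and motifs, and domains without peaks near starts. The smallest peaks rest on 10 fragments, which limits their ranking.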

Other observations

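The tests in this part were chosen after the data were examined, each before its own result was known, and ran on the same lists. The design names no second group with peaks, and no biological difference between groups was tested.

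The first 100 kb of chromosomes were examined because the strongest and the third strongest CTCF peak lay there, on chromosomes 16 and 9. The far ends of chromosomes were not examined. The first 100 kb held 37 CTCF peaks on 13 chromosomes, with a median fold enrichment of 10.0 against 9.59 elsewhere. Of these, 9 (24.3%) exceeded 19.9, the 90th percentile elsewhere. This share includes the 2 peaks that prompted the look, so it is a description only. For H3K27ac, 3 of 41 such peaks (7.32%) exceeded the 90th percentile elsewhere, and the median was 4.19 against 4.55. Of 102 CTCF peaks with a local background more than 10 times the genome-wide level, 38 lay on the unplaced contig gl000220, which carries ribosomal DNA, where the median background of all CTCF peaks was 31.7 times that level. Their fold enrichments were low, with a median of 2.06 over the 102 peaks. For H3K27ac, 18 of 30 such peaks lay on this contig. On chromosome X, CTCF peaks had a lower median fold enrichment than on the autosomes (7.19 against 9.76), and H3K27ac peaks a higher one (6.23 against 4.55). Median local backgrounds were lower there, at 2.18 against 3 for CTCF and 3.18 against 3.89 for H3K27ac. How far lower input changed these fold enrichments was not tested.

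The weakest decile of CTCF peaks overlapped H3K27ac more often than the fifth and sixth deciles, by 6.04 percentage points (SE 0.715). One explanation was high local input background, which lowers fold enrichment. Among the 11178 CTCF peaks at the genome-wide background, the lowest decile still overlapped more often, by 4.33 points (SE 1.16; 12.7% against 8.37%), which argues against background as the whole cause. Acetylated chromatin carried along in the CTCF pull-down without CTCF binding remains open: it calls for no dip in H3K27ac coverage at the summit, and the ratio in this decile was 1.00099 (SE 0.0213), against 0.560 in the strongest decile. Some weak CTCF peaks may thus mark open acetylated chromatin and not CTCF sites, which a motif search could test.

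Coverage by H3K27ac peaks dipped at CTCF summits. H3K27ac peak edges placed without regard to CTCF binding would give the same ratio at strong and weak CTCF peaks, but the ratio in the strongest decile minus that in the weakest was −0.441 (SE 0.029). Peaks split in pieces by the caller's threshold were tested by joining H3K27ac peaks less than 500 bases apart: the ratio rose from 0.724 to 0.842 (SE 0.0068) and stayed below 1. Splits of less than 500 bases may therefore account for part of the dip but not for all of it. Wider splits, and peaks shortened at an edge by the threshold, were not tested. The join thus cannot decide whether the caller accounts for the rest. A stretch without acetylated nucleosomes at bound CTCF is a hypothesis that these tests leave open.

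A further hypothesis was that CTCF sites separate acetylated from unacetylated stretches. One-sidedness was measured as the absolute difference of H3K27ac bases left and right of a summit over their sum, from 2.5 to 100 kb away, at 12261 CTCF summits with at least 5 kb of H3K27ac in that range. Its mean was 0.521, above all 1000 sets of positions shifted by 200 to 500 kb and matched for the amount of H3K27ac (100%), which averaged 0.499 (95% range 0.492 to 0.505). The difference is small, and genes or other borders near CTCF sites may give the same value, which was not tested.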
